A study of Mus musculus with 3 samples.

How the data were processed

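Chromatin immunoprecipitation followed by sequencing (ChIP-seq) had been carried out on primary mouse pancreatic islets, the endocrine cell clusters of the pancreas. Islets came from control mice and from mice that lack Arid1a in the pancreas. Arid1a is a DNA-binding subunit of the SWI/SNF chromatin remodelling complex, and HDAC6 is a deacetylase best known for acting on tubulin in the cytoplasm. Per the labels, collected islets were pooled, chromatin was fixed with formaldehyde and sonicated, and an antibody against Arid1a was used in control and in knockout islets. A further library was made from control islets with an antibody against HDAC6, whose name is spelled with transposed letters in the labels and was read as HDAC6 from the series title. Each of the 3 groups held 1 library, so no value has a replicate error and no test compares the genotypes or the antibodies as such.

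The deposited data were 1 peak list per library, each called by the authors against a library without immunoprecipitation (no-IP), per the peak names in the files. Per the submitters' processing notes, the genome build was mm10 and the tools included cutadapt, Bowtie, Bowtie2 2.2.6, bedtools and edgeR 3.4.6, listed without their roles. The peak caller and its settings were not given in the sources used here, and the column names are those of a MACS peak table. The pileup column is the deposited signal, the number of ChIP fragments covering the summit, in whole numbers and without scaling, per the file headers and values. The fold enrichment deposited by the authors is the ratio of that pileup to the local no-IP background. The deposited lists also give the −log10 of the p-value and of the q-value of each peak. Fold and q are the authors' values and served to describe, rank, filter and test peaks within a list. Fold was also used to recover the no-IP background. Positions are printed 1-based, as deposited. A list of called peaks gives no signal at places where no peak was called, so the absence of a peak is not a measured level of 0.

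The number of reads per library is not in the lists. The no-IP background at each summit was recovered as (pileup + 1) / fold − 1, on the assumption that 1 was added to both terms before the division. A Poisson p computed from the pileup and this background agreed within 1% with the deposited −log10 p for 237 of 250 peaks of the control Arid1a list, 363 of 384 of the knockout Arid1a list and 219 of 236 of the control HDAC6 list. The smallest background of a list, 1.64, 1.23 and 1.50 fragments in that order, was taken as a measure of relative depth, which assumes that it reflects the genome-wide level of that library.

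Peaks counted as shared when they overlapped by at least 1 bp. The shared count was compared with 10000 random placements of the second list in a one-sided shuffle test (a permutation test of positions) that kept every peak on its chromosome and at its length. Every position on a chromosome was taken as equally likely, so the test does not allow for places where peaks are more readily called. Chromosome lengths for the placements were taken as the largest gene end on each chromosome, and peaks on mitochondrial DNA and unplaced contigs were left out of this test. Fisher's exact test (two-sided) compared the share of control Arid1a peaks found in the HDAC6 list between those called and those not called in the knockout list. Differences of median fold were tested with a two-sided permutation test of 100000 resamples. Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only and treat neighbouring peaks as independent. Families of tests were adjusted by the Benjamini-Hochberg method. These tests take peaks of single libraries as their units and describe those libraries.

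Genes came from a RefSeq table of assembly GRCm38.p6, which has the same chromosome coordinates as mm10, with 21896 protein-coding gene spans. The table used here holds no strand, exons or transcription start sites. The split into promoter, exon, intron and intergenic peaks fixed beforehand was therefore replaced by the share of peaks inside or within 1 kb of a protein-coding gene span, compared with 10000 random placements. Each peak was assigned to the nearest protein-coding gene, at any distance. Before the data were examined, 13 gene lists with 270 genes were fixed (beta cell, other endocrine, endocrine development, acinar, ductal, exocytosis, insulin signalling and glucose metabolism, SWI/SNF, deacetylases, cytoskeleton and HDAC6 partners, stromal with vascular and immune, housekeeping, and pancreatic neoplasia), of which 269 genes were found in the table. Each list was tested in each peak list by a one-sided Fisher's exact test against all protein-coding genes, with adjustment over the 39 tests.

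Peaks named in the text follow a rule fixed at the same time. It takes the 10 peaks of highest fold per list, the 15 of highest control Arid1a fold among peaks shared with each other list, up to 10 found in all 3 lists, peaks assigned to genes of the fixed lists, and peaks at Arid1a or Hdac6. Some peaks that the rule takes are not reported here. The stretch between Hrh1 and Atg7, the other dense stretches, the sites of very high background, the background limit of 10 and the grouping of chromosomes 5, 6, 14 and X were chosen after the values were seen. Alternatives fixed beforehand were an overlap of 50% of the shorter peak, a reciprocal overlap of 50%, a distance within 1 kb, the part of each list with fold above its median, placement anywhere in the genome, autosomes alone, merging of peaks within 1 kb, a distance of 5 kb from gene spans and a distance of 10 kb for the gene lists. Fold rather than p was chosen as the stricter criterion once its column was known. The shuffle and gene assignment were tested on simulated data. Of 100 simulated pairs with the lengths and chromosomes of the control and knockout Arid1a lists and no planted overlap, 0 gave a shuffle p below 0.05. Both simulated lists were placed at random, as in the shuffle itself, and with fewer shuffles. A count of 0 was therefore likely from the start and does not check the test on clustered peaks. All 20 planted shared peaks were found, and 200 of 200 genes were returned at their own position. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.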

Results

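Called ChIP-seq peaks of mouse islets came from 3 libraries. There was 1 for each of control islets with an Arid1a antibody, Arid1a-knockout islets with the same antibody, and control islets with an HDAC6 antibody. The lists held 250 peaks over 141 kb for control Arid1a, 384 peaks over 190.1 kb for knockout Arid1a and 236 peaks over 128 kb for control HDAC6. Median peak lengths were 461.5 bp, 374.5 bp and 391.5 bp in that order. The median pileup at the summit was 19, 15 and 20 fragments, and the smallest pileup called was 9, 8 and 9 fragments. Median fold over the no-IP background, as given by the authors, was 4.85, 4.94 and 5.03. The q-value exceeded 0.05 for 6 control Arid1a peaks and 3 control HDAC6 peaks, up to 0.0769 and 0.0642, and for 0 knockout Arid1a peaks. No peak of any list lay inside, or had as its nearest gene, Arid1a (chromosome 4, 133679008 to 133756769) or Hdac6 (chromosome X, 7930116 to 7948047). A peak list does not measure expression, so the loss of Arid1a in the knockout library was not checked here.

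The first comparison asked which regions called with the Arid1a antibody in control islets were also called in Arid1a-knockout islets. The peak of highest fold in control islets lay beside Neurog3, the transcription factor that starts endocrine differentiation in the pancreas, and had no counterpart in the knockout list. It spanned chromosome 10, 62131842 to 62132834 (mm10), 256 bp from the Neurog3 gene span (62133090 to 62134763), with a pileup of 285 fragments and a fold of 92.7 over a background of 2.08 fragments. A DNA piece with fixed ends stays open for this control peak (weighed below). The nearest knockout peak was 9497 kb from Neurog3. By contrast, sites beside Pdx1, a transcription factor of beta cell identity, and in the stretch between the histamine receptor gene Hrh1 and the autophagy gene Atg7 were called in both genotypes. In all, 103 of 250 control Arid1a peaks (41.2%, 95% interval 35.04% to 47.6%) overlapped a knockout peak, and the knockout list was the longer of the 2 lists.

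At Pdx1 (chromosome 5, 147270097 to 147275848), the control Arid1a list had 2 peaks outside the gene span. The peak at 147266053 to 147266901, with a fold of 5.67 and a pileup of 15, overlapped a knockout peak at 147266012 to 147266412 with the same pileup and a fold of 6.89. The peak closer to the gene, at 147267768 to 147268271, had a fold of 3.86 and no overlap in another list. Of the 10 control Arid1a peaks of highest fold, 8 were in that list alone. They included a peak inside Mocos, the molybdenum cofactor sulfurase (chromosome 18, 24677131 to 24677470, fold 45.3, pileup 127). A further 5 lay outside genes and were nearest to Kif6, Cp, Kcnj5, 1700010I14Rik and Foxd1, with folds of 13.3 to 23.5.

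In the knockout list no fold exceeded 15.6. Its highest peak was 1217 kb from Grik2 on chromosome 10 (47876471 to 47876953) and was shared with control HDAC6. A peak inside Cd96, an immune receptor gene (chromosome 16, 46078344 to 46078718), had a fold of 14.5 and was in the knockout list alone, as were a peak 5489 bp from Dynlrb1, a peak nearest to Cylc2 and a peak on an unplaced contig. Peaks nearest to Crp, Trps1, Ipmk, Gsdmc and Hrh1 completed the knockout top 10 and were each found in all 3 lists. Among peaks shared by control and knockout Arid1a, those of highest control fold were in the Hrh1 to Atg7 stretch, with folds of 18.8, 13.0 and 12.0, and at a site 1322 kb from Iftap on chromosome 2 with a fold of 12.1. Outside that stretch, the next shared sites were nearest to Gm20812 on chromosome Y (9.61), Crp (9.41), Gm51598 (9.36), Tbc1d2b (9.11), Gm6729 (9.03), Ccng1 (9.03), V1rd19 (8.92) and Ipmk (8.83).

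On placed chromosomes 95 control Arid1a peaks overlapped knockout peaks, against a mean of 0.0516 and at most 3 in 10000 random placements (one-sided permutation test of positions, p = 0.0001, the smallest it can give, adjusted p = 0.0001 over 3 pairs). Control Arid1a peaks shared with the knockout had a median fold of 5.49 against 4.69 for the rest, a difference of 0.794 (two-sided permutation test, p = 0.000830, adjusted p = 0.00131). That difference was −0.111 (permutation p = 0.648) without the peaks between Hrh1 and Atg7, and 1.41 (permutation p = 1e-05, the smallest it can give) among peaks with a no-IP background under 10. These limits were not applied together. With 1 library per genotype, a peak called in 1 list and not in the other has no replicate check.

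**Figure D1:**
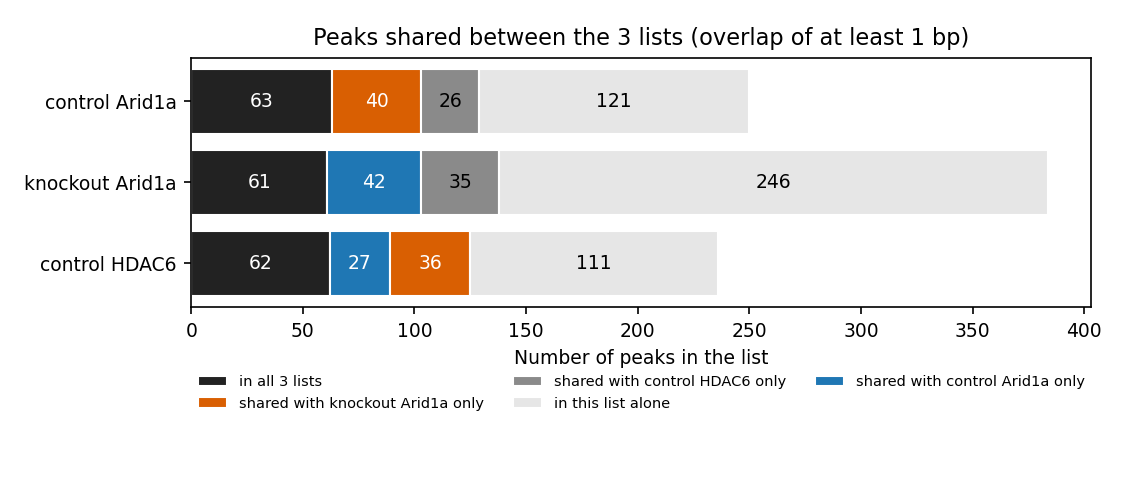
Number of peaks in each list (horizontal axis, peaks) by the lists they overlap by at least 1 bp. In the control Arid1a bar 63 peaks are in all 3 lists and 121 in that list alone, and in the knockout bar 246 of 384 peaks are in that list alone.

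The second comparison asked which regions were called with both the Arid1a and the HDAC6 antibody in control islets. The Neurog3 site was the peak of highest fold for both antibodies. With the HDAC6 antibody it spanned 62131839 to 62132834 with a pileup of 1164 fragments and a fold of 279.6 over a background of 3.17, and its lower end differed by 3 bp and its upper end by 0 bp from the Arid1a peak. The summits, at 62132717 for Arid1a and 62132190 for HDAC6, were 527 bp apart, and the pileups differed 4.08-fold. A DNA piece with fixed ends, such as an amplicon or a plasmid insert, stays open for this site. Both lists also shared the Hrh1 to Atg7 stretch and a site 50.0 kb from Pls3, an actin-bundling protein gene on chromosome X. That site (75734596 to 75735607, control Arid1a fold 11.8) was not in the knockout list. Another control Arid1a peak, 40.7 kb from Pls3 (75744573 to 75744933, fold 4.93), overlapped a knockout peak of fold 5.77 and no HDAC6 peak. Overall 89 of 250 control Arid1a peaks (35.6%, 29.7% to 41.9%) overlapped an HDAC6 peak, which were 89 of 236 HDAC6 peaks (37.7%, 31.5% to 44.2%).

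The HDAC6 peaks inside 2 beta cell genes, Abcc8 and Cpe, had no counterpart in the Arid1a lists. The same held for 111 of all 236 HDAC6 peaks (47.0%). Abcc8, the sulfonylurea receptor subunit of the beta cell potassium channel, held an HDAC6 peak at chromosome 7, 46138102 to 46138427, with a fold of 11.2 and a pileup of 34. Cpe, the carboxypeptidase of prohormone processing, held a weaker peak at chromosome 8, 64622945 to 64623298, with a fold of 5.03 and a pileup of 12. The smallest pileup called in the HDAC6 list was 9. The nearest control Arid1a peaks were 1820 kb from Abcc8 and 7722 kb from Cpe, and the HDAC6 peak nearest to Pdx1 was 3867 kb from it. The HDAC6 peak of second-highest fold was 140 kb from Gli2, an effector of hedgehog signalling, at chromosome 1, 119194745 to 119195097 (fold 17.4), and was in the HDAC6 list alone. The remaining HDAC6 top 10 lay nearest to Atg7, Hrh1, Pls3, Iftap, Grik2, Gsdmc and Trps1, with folds of 11.6 to 15.4, and each of these was shared with at least 1 Arid1a list.

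On placed chromosomes 81 control Arid1a peaks overlapped HDAC6 peaks, against a mean of 0.0371 and at most 2 at random (permutation of positions, p = 0.0001, adjusted p = 0.0001). Peaks shared with HDAC6 had a median fold of 5.56 against 4.69 for the rest (difference 0.872, permutation test, p = 0.00131, adjusted p = 0.00131). That difference was 0.213 (permutation p = 0.354) without the Hrh1 to Atg7 stretch and 1.41 (permutation p = 1e-05) among peaks with a background under 10. These limits were not applied together. All 3 lists name a no-IP library as their background, and the labels do not say whether it was the same library or from which genotype. If it was the same, part of the overlap may come from it.

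**Figure D2:**
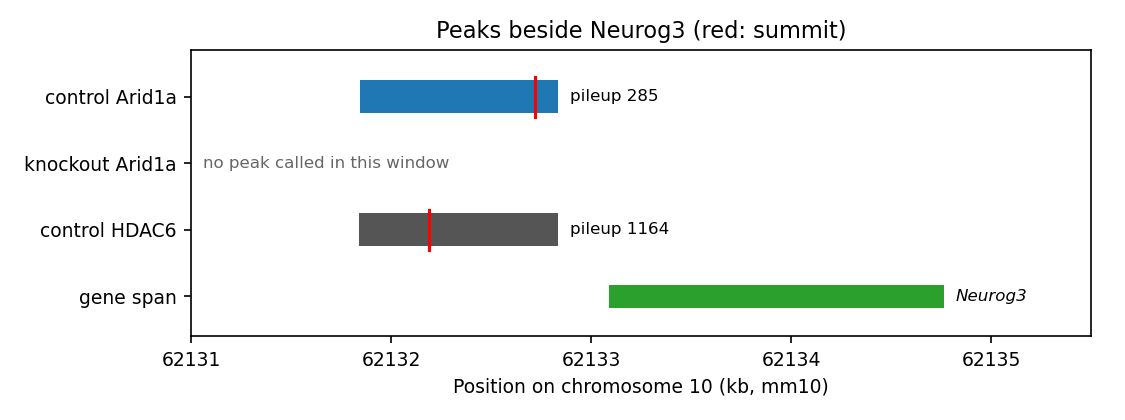
Map of chromosome 10 beside Neurog3 (horizontal axis, position in kb, mm10). Bars show the called peaks of each list with the summit in red and the Neurog3 gene span in green. The control Arid1a and HDAC6 bars have nearly the same ends, with pileups of 285 and 1164 fragments.

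The remaining pair, knockout Arid1a and control HDAC6, differed in both antibody and genotype and gave a level against which to set the other overlaps. Sites nearest to Grik2, Crp, Trps1, Ipmk, Gsdmc and Iftap were called in both. Of the HDAC6 peaks, 98 of 236 (41.5%, 35.2% to 48.1%) overlapped a knockout Arid1a peak, beside the 37.7% that overlapped a control Arid1a peak, and the intervals overlapped. Counted over the Arid1a lists, of which the knockout list is the longer, the order was the opposite. An HDAC6 peak overlapped 96 of 384 knockout peaks (25%, 20.7% to 29.64%) and 89 of 250 control peaks (35.6%, 29.67% to 41.9%). These intervals only just failed to overlap, and they treat neighbouring peaks as independent. The shared counts were close, so this order reflects the lengths of the 2 lists. On placed chromosomes 88 knockout peaks overlapped HDAC6 peaks, against a mean of 0.0405 and at most 3 at random (permutation of positions, p = 0.0001, adjusted p = 0.0001). The control Arid1a peaks also found with HDAC6 were mostly those also called in the knockout. Of the 103 control peaks called in the knockout, 63 were in the HDAC6 list (61.2%, 51.1% to 70.6%), against 26 of the 147 not called there (17.7%, 11.9% to 24.8%), an odds ratio of 7.33 (Fisher's exact test, p = 2.21e-12, across peaks of single libraries). The odds ratio was 4.64 among peaks of higher fold in each list. It was 5.14 among peaks with a background under 10 (51.9% against 17.4%). After peaks within 100 kb were merged it was 16.2, but merged stretches are longer than single peaks and so overlap more easily. The 26 peaks in both control lists and not in the knockout list had a median control Arid1a fold of 5.40. They included the Neurog3 site and the site 50.0 kb from Pls3.

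The stretch with the most peaks in each of the 3 lists was the 159.8 kb between Hrh1 and Atg7 on chromosome 6 (114483299 to 114643126). It held 30 control Arid1a peaks (12.0%, 8.24% to 16.7%), 20 knockout peaks (5.21%, 3.21% to 7.93%) and 24 HDAC6 peaks (10.2%, 6.63% to 14.8%), in 0.00587% of the placed genome length. Of these, 14 in each list were in all 3 lists. Median fold there was 6.40, 6.82 and 6.37, over median backgrounds of 3.149, 2.504 and 2.639 fragments. These backgrounds were 1.92, 2.04 and 1.76 times the smallest of each list. The peak of highest fold in the stretch for control and knockout Arid1a was at 114560825 to 114561470 and 114560848 to 114561481, with folds of 18.8 and 14.7, and the HDAC6 peak at 114560849 to 114561483 had a fold of 15.2.

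**Figure D3:**
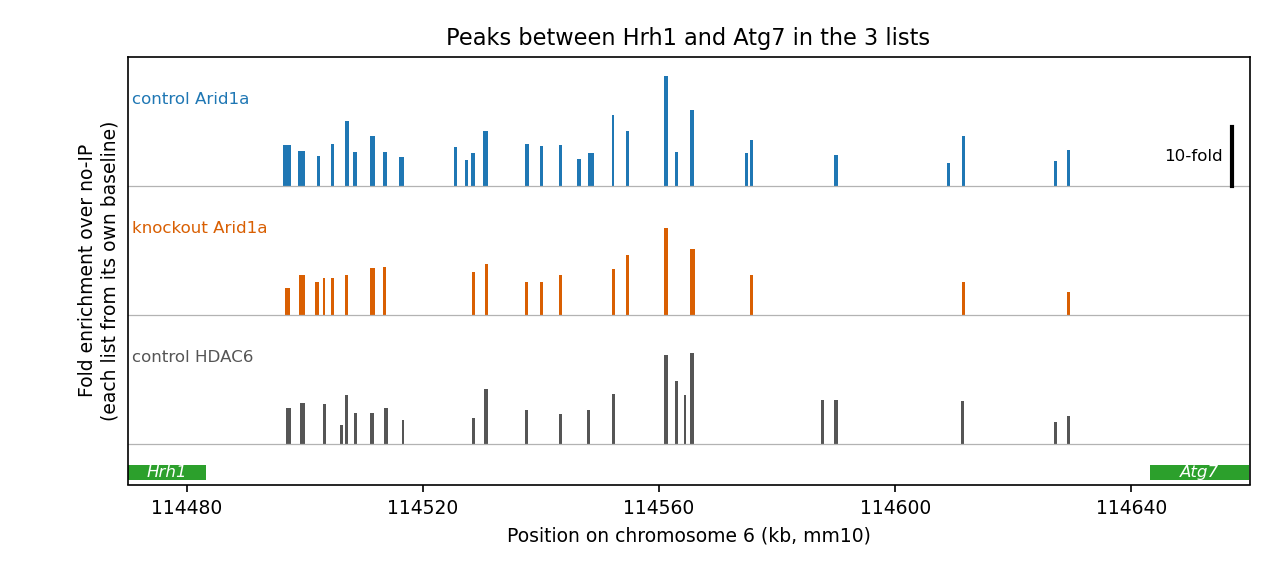
Peaks between Hrh1 and Atg7 on chromosome 6 (horizontal axis, position in kb, mm10), with bar height showing fold enrichment over no-IP from a separate baseline for each list and a bar marking 10-fold. The 3 lists have 30, 20 and 24 peaks there, 14 of them in all 3 lists.

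Dense stretches on chromosomes 5 and 14 lay among numbered predicted genes. Between 15458680 and 15690733 of chromosome 5, around Speer4c, Speer4d and predicted genes of the same neighbourhood, the lists had 18, 17 and 11 peaks in the order control Arid1a, knockout Arid1a and HDAC6. On chromosome 14, between 4070133 and 4207464 around Gm2974 and Gm32966, they had 10, 9 and 4 peaks. The median no-IP background was 2.75, 3.22 and 3.88 times the smallest of each list in the chromosome 5 stretch. In the chromosome 14 stretch it was 1.26, 1.05 and 1.18 times the smallest. Chromosomes 5, 6, 14 and X together held 58.8% (52.4% to 65.0%), 43.5% (38.5% to 48.6%) and 41.1% (34.8% to 47.7%) of the peaks, against 21.9% of the placed length, and 39.9%, 35.6% and 30.4% after peaks within 100 kb of each other were merged. Chromosome X alone held 18.0%, 15.9% and 11.9% of the peaks against 6.27% of the length.

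A separate set of peaks stood on very high no-IP background. Background was 10 fragments or more at 27 control Arid1a peaks (10.8%), 43 knockout peaks (11.2%) and 32 HDAC6 peaks (13.6%), and 22, 21 and 22 of these were in all 3 lists. The highest pileup of each list was on chromosome 2 near 98666855, 1035 kb from Lrrc4c, with 55483, 59339 and 58802 fragments and folds of only 1.67, 2.42 and 1.90. On chromosome 9, between 3000022 and 3038245 with Alkbh8 as the nearest gene, 9, 15 and 13 peaks had median backgrounds of 1808, 903 and 1144 fragments. The Neurog3 peaks stood apart from these, with pileups of 285 and 1164 over backgrounds of 2.08 and 3.17 fragments.

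**Figure D4:**
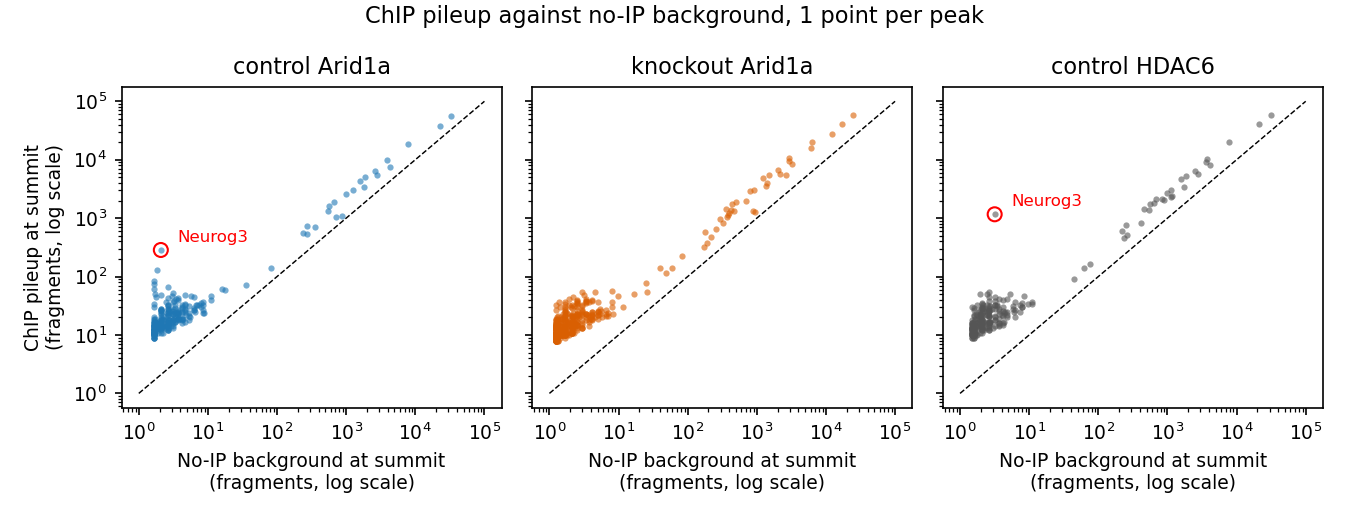
ChIP pileup at the summit (vertical axis, fragments, log scale) against the recovered no-IP background (horizontal axis, fragments, log scale), 1 point per peak and 1 panel per list, with a dashed line of equality. The Neurog3 peak, circled, has a background of 2.08 fragments in control Arid1a and 3.17 in control HDAC6, and the knockout panel has no such point.

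Peaks lay inside or near protein-coding genes less often than random places did. The share inside or within 1 kb of a gene span was 21.1% of 242 control Arid1a peaks (16.1% to 26.8%), 24.0% of 371 knockout peaks (19.7% to 28.7%) and 25.6% of 227 HDAC6 peaks (20.01% to 31.7%), against 39.4%, 39.0% and 39.5% of random placements (two-sided permutation of positions, p = 0.0002 for each list, the smallest it can give). Each peak was placed on its own, so clustered peaks counted as independent. After peaks within 100 kb were merged, the control Arid1a share was 28.1% against 40.7% at random (permutation p = 0.0032). The knockout share was then 27.5% against 39.2% (permutation p = 0.0004), and the HDAC6 share 32.9% against 39.8% (permutation p = 0.0852). Without merging, the lists did not differ detectably from each other in this share (Fisher's exact test, adjusted p = 0.648, 0.648 and 0.696). Numbered predicted genes (Gm genes) were the nearest gene of 24.4%, 18.9% and 16.3% of the peaks and made up 6.06% of the genes. The share of random places nearest to such a gene was not computed, and clustered peaks were counted singly here.

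Of the 39 tests of the fixed gene lists, 0 passed an adjusted p of 0.05 and 2 had an unadjusted p below 0.05, both of them for beta cell genes. The tests took every gene as equally likely to be the nearest, whatever its length or the gap around it. Their expected counts and p-values do not allow for long or isolated genes. In the HDAC6 list 3 of 31 beta cell genes were the nearest gene of a peak, against 0.238 expected (Fisher's exact test, p = 0.00170, adjusted p = 0.0664), namely Abcc8, Cpe and the insulin gene Ins1. In the control Arid1a list 2 of 31 were, Pdx1 and Ins1, against 0.212 expected (Fisher's exact test, p = 0.0190, adjusted p = 0.371), and the same 2 genes were assigned in the knockout list. The peak assigned to Ins1 lay 363 kb from the gene and was called in all 3 lists. No peak lay within 10 kb of Ins2 or of the glucagon gene Gcg in any list. The list of endocrine development genes had 1 gene in each control list, Neurog3, and 0 in the knockout list. The knockout list had peaks inside Cftr, the chloride channel of ductal cells (chromosome 6, 18266474 to 18266808, fold 8.54), and inside Hdac7 (chromosome 15, 97830964 to 97831335, fold 3.89), the 1 ductal and 1 deacetylase gene assigned to its peaks. It also had peaks assigned to Irx2 of the other endocrine list, Syt1 of the exocytosis list and Gpd2 of the glucose metabolism list, which were 77.6 to 235 kb away. The exocytosis gene Syt4 was assigned an HDAC6 peak 56.7 kb away. These 5 lists had 0 other genes assigned in any list. Acinar, SWI/SNF, cytoskeleton and HDAC6 partner, stromal, vascular and immune, housekeeping and pancreatic neoplasia genes were assigned to 0 peaks in each of the 3 lists.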

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

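Merging within 100 kb, leaving out the Hrh1 to Atg7 stretch, the limit on background, the shift that keeps the spacing of peaks, and each alternative for the median fold were chosen after seeing the data. The 3 overlaps of peak lists passed the permutation test of positions (p = 0.0001, the smallest it can give) under each alternative run. Each alternative placed peaks without regard to where peaks are more readily called. Among peaks of higher fold in each list (125, 192 and 118 peaks for control Arid1a, knockout Arid1a and HDAC6), the shared counts were 53, 42 and 46 for control with knockout Arid1a, control Arid1a with HDAC6 and knockout Arid1a with HDAC6, which follows from the fewer peaks. Merging within 100 kb left 138 control Arid1a peaks and shared counts of 58, 48 and 61, and put 39.9%, 35.6% and 30.4% of the peaks on chromosomes 5, 6, 14 and X. With that merging the HDAC6 share in or near genes was 32.9% against 39.8% at random (permutation p = 0.0852), and the cause was not tested. Without the Hrh1 to Atg7 stretch, whose median fold of 6.40 lies above the 4.85 of the control Arid1a list, the difference in median fold was −0.111 (permutation p = 0.648) for peaks shared with the knockout and 0.213 (p = 0.354) for peaks shared with HDAC6. With peaks of background under 10 alone, it was 1.41 for each (permutation p = 1e-05, the smallest it can give). These limits were not applied together, so the 27 control Arid1a peaks of background 10 or more remained when the stretch was left out. Of these, 22 were in all 3 lists, and none had a fold above 3.99. The odds ratio of the HDAC6 overlap split by the knockout ranged from 4.64 (peaks of higher fold) to 16.2 (merged within 100 kb), and 0 gene list tests passed the adjusted threshold under any alternative. No paired analysis was possible because each group has 1 library, and no library could be left out for the same reason. The smallest pileups called, 8 and 9 fragments, limit what could be detected at these depths.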

Other observations

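All tests in this part were chosen after the data had been seen.

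The peak beside Neurog3 was called in both control lists and not in the knockout list. A lower depth of the knockout library is argued against, since the control Arid1a pileup scaled by the ratio of the smallest backgrounds (0.749) would be 213 fragments there, where 8 sufficed for a call. A DNA piece with fixed ends, such as an amplicon or a plasmid insert, stays open, as the ends of the Arid1a and HDAC6 peaks differed by 3 bp in sum although the pileups differed 4.08-fold. There were 21 other shared peaks with a pileup of at least 285, the lower of the Neurog3 pileups, in both lists. Their median was 29 bp, and 1 of the 21 also had 3 bp or less, with nearly equal pileups of 5396 and 5653. All 21 had a background of 10 or more, against 2.08 and 3.17 at Neurog3. Below a background of 10, the next highest pileup was 127 in control Arid1a and 55 in control HDAC6. No shared peak was therefore like Neurog3 in both height and background, so this comparison cannot decide the question. The 13 shared peaks with pileups over 1.5-fold apart had 41 bp or more, but only 2 of them reached 285 in both lists. Arid1a-dependent binding stays open as a hypothesis, because 1 knockout library cannot separate genotype from the library.

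Many peaks were shared between lists that differ in antibody, genotype or both. Chance positions of clustered peaks, spread evenly along each chromosome, are argued against. The highest count in 10000 shifts that keep the spacing of peaks was 12, against at least 81 observed. The shifts took every position as equally likely to be called, so they cannot weigh chance among places prone to be called in any library. Of the 250 control Arid1a peaks, 63 were in all 3 lists, so some regions were called with both antibodies and in both genotypes. Whether such regions account for the rest of the sharing stays open, because the shares went opposite ways with the list counted. The knockout Arid1a list shared 41.5% of the HDAC6 peaks against 37.7% for the control Arid1a list. Counted the other way, 25% of knockout against 35.6% of control Arid1a peaks were shared with HDAC6, and the knockout list is the longer. Arid1a left in the knockout islets stays open. Of the control Arid1a peaks, 40 were shared with the knockout alone and 26 with HDAC6 alone (exact McNemar test, two-sided p = 0.109). This test cannot decide the question, because the knockout list is longer than the HDAC6 list (384 against 236 peaks). It also takes neighbouring peaks as independent. Signal at places without a called peak would be needed to weigh these further.

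The control Arid1a list alone had 8 of its 10 peaks of highest fold, with folds of 13.3 to 45.3, including that inside Mocos. A higher depth of that library is argued against, since the smallest of their pileups scaled to the knockout library was 25.5 fragments against the 8 that sufficed there. Repeated sequence stays open, because the low median no-IP background of these peaks, 1.69 fragments, follows from their choice by fold, and no control Arid1a peak with a background of 10 or more had a fold above 3.99. Stacks of fragments at single positions could not be excluded, as the median length was 384.5 bp against 474 bp for the 30 other peaks with pileups of 30 to 150 and a background under 10 (two-sided permutation test, p = 0.104). Binding that depends on Arid1a remains an untested hypothesis for these sites, and it would need further libraries of both genotypes.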
